A study of Arabidopsis thaliana with 2 samples.

How the data were processed

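Chromatin of Arabidopsis roots expressing SHR-GFP was precipitated with anti-GFP, and the recovered DNA was amplified by random-primed whole-genome amplification and hybridised beside input DNA, per the labels' protocols. Each of the 2 arrays carried both, with Cy5 on the precipitated DNA and Cy3 on the input, and no dye swap. Both arrays belong to 1 group and are called replicate 1 and replicate 2. The labels describe them as biological replicates.

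The authors deposited the scanner output of each array, with red (Cy5) and green (Cy3) intensity values per feature, made with Agilent Feature Extraction. The submitters' processing notes give version 9.0, and the file headers give version 9.1.3.1 with protocol CGH-v4_91. Per the file headers, the processed intensity is background-subtracted and linearly dye-normalised, and a multiplicative surface trend was fitted on replicate 1 but not on replicate 2. The deposited value table holds the log10 ratio of red over green of the same arrays: it differed from the scanner files' log10 ratio by at most 0.00427, its median is 0 on both arrays, and its scale and direction are those of the scanner files. In that log10 ratio, per the file headers and values, features whose 2 channels both hold surrogate values are set to 0. There were 14977 such features on replicate 1 (6.29%) and 13344 on replicate 2 (5.61%), whose processed intensities give a median log2 ratio of 0.03 and 0.72.

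The log2 ratio of the processed intensities (red over green) was centred on the median of each array, after leaving out control features and 1658 and 5656 outlier-flagged features. Saturated features were kept. Features of 1 probe were averaged, which left 231022 probes measured on both arrays. Windows were means over the probes within 400 bp either side of each probe, with at least 3 probes (median 4). Probes, windows and gene neighbourhoods were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided) and adjusted by Benjamini-Hochberg at 0.05. With 2 arrays each test has 1 residual degree of freedom, and the spread is shared across features through the prior of eBayes (39.3 prior degrees of freedom for windows, 9.66 for neighbourhoods). Windows past the threshold and at least 2-fold from 0 were joined into regions when their centres lay within 800 bp. Values are given as mean ± SD over the 2 arrays. The R package data.table (version 1.17.8), pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 were used for tables and plots. On simulated arrays with 200 shifted regions, built from the differences between the 2 arrays, the window test called 28.0% of 50 regions shifted by 0.585, 96.0% of those shifted by 1.0 and 100.0% of those shifted by 1.5 or 2.0 on the log2 scale. Of its 939 calls there, 189 (20.1%) had centres more than 800 bp from the centre of any shifted region, where the adjustment aims at 5%. On simulated arrays with no shift it called 15 of 203849 windows, 0 of them at 2-fold. Differences between the arrays leave out whatever both arrays share, so this count does not cover false calls from shared dye, input or probe effects. The simulated arrays also had equal spread, where the probe SDs were 0.40 on replicate 1 and 0.53 on replicate 2.

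The probes are named by position with no gene and no build. Gene ends in the TAIR10.1 table and the array's coordinates were compared in bins of 500000 bp for the shift that best aligned probes with the gaps between genes. Where the best shift was within 60 bp the coordinates were taken to coincide: 48.0 Mb with 113212 probes (47.7%) and 13047 of 27758 genes, including 95 of the 208 genes of the 12 lists. No coordinates were converted, and regions elsewhere are given by position without a gene. The table gives no strand, so the planned promoters were replaced by gene neighbourhoods: the gap on each side up to 3000 bp, not inside another gene, plus 500 bp inside each gene end. Distances from transcription start sites were not analysed here. For a neighbourhood the mean over its probes was tested, and its highest and lowest windows are given.

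Gene lists were fixed before the data were examined and tested with limma's camera (preset correlation 0.01, and an estimated correlation) and by the percentile of the list's median among 10000 random lists matched on windows per gene. The lists were published SHR targets, IDD family, GRAS family, cytokinin, vascular, brassinosteroid and gibberellin, cell cycle, endodermis, epidermis and root cap, photosynthesis, seed storage and highly transcribed root genes. Named genes followed a rule set at the same time: all published targets, SHR, the 10 highest neighbourhoods by the weaker array among those with a window at least 2-fold higher (1 qualified), the 3 lowest, and the leading member of each list. The same rule with the sign turned, and the percentiles of lowest windows, were added after the data were seen, as was the test of region positions inside genes. Motifs were searched in the probe sequences only.

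The alternatives set before the data were examined were normexp background correction (offset 50), loess within arrays (span 0.3), centring on the mode, the deposited value table, only probes well above background, no saturated features, removal of the GC trend, half-widths of 250 and 600 bp, window medians, eBayes with trend and robust, an adjusted p of 0.01, a 1.5-fold minimum, joining within 400 bp, at least 5 probes per neighbourhood, larger top lists, and each array alone. Leaving out features with surrogates in both channels was added later.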

Results

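The data came from roots of Arabidopsis thaliana seedlings of the Columbia ecotype, aged 6 days, that carried a GFP fusion of SHORT-ROOT (SHR) under its own promoter in the shr-2 mutant. SHR is a GRAS-family transcription regulator that is made in the stele and moves into the endodermis. Chromatin was precipitated with an antibody against GFP and set against input DNA on a custom promoter microarray, with the question of which genes SHR occupies in the root. The design held 1 group of 2 arrays, described in the labels as biological replicates, with no array of a line without GFP and no exchange of the dyes. Each array carried 237976 features other than controls, for 237575 distinct probes of 60 bases with a median spacing of 158 bp. Of these features, 92.9% (Cy3) and 91.7% (Cy5) were well above background on replicate 1, and 94.2% and 87.7% on replicate 2. With 2 arrays, their number limits the precision of every value.

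The labels assign Cy5 to the DNA from the precipitation and Cy3 to input DNA, so the log2 ratio of Cy5 over Cy3 would be positive where SHR-GFP was enriched. The lowest windows of the 4 measured loci, of 12 known as SHR targets before this series, were called below 0, as given next. A lowest window tends to lie below 0 in any gene, and random lists matched on windows per gene had a median of -0.38. The sign alone therefore does not go against the labels. The percentile planned in advance was that of the highest windows. There the 4 loci had a median of 0.11, at percentile 4.22, where matched random lists had a median of 0.26. Only these 4 loci carry that value. Which channel held the precipitated DNA is left open here. Signs are printed throughout as measured, Cy5 over Cy3, and the channels are called the DNA labelled ChIP (Cy5) and the DNA labelled input (Cy3). All coordinates are those of the array design, whose genome build is not given in the sources used here. Genes are named only in the part of the genome, 48.0 Mb, where those coordinates coincided with the TAIR10.1 gene table.

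The first question was whether published SHR targets stood apart. Of the 12 genes on that list, 4 lay in the part of the genome where genes could be named, and each of the 4 had a window that was significantly lower in the DNA labelled ChIP than in the DNA labelled input, with both arrays below 0. None of the 4 had a window that was significantly higher, but only 69 of 11580 gene neighbourhoods held one, so that absence says little. The lower calls depended on the processing: none of the 4 passed with the deposited value table, centring on the mode or a trended and robust variance prior, and only MGP passed after normexp background correction. MIR165a and JKD also missed the threshold after loess, with window medians, at an adjusted p of 0.01 and without features at surrogate values in both channels. MGP (AT1G03840), which encodes a zinc-finger protein of the IDD family, had its lowest window at chromosome 1, 971524 to 972292, with a log2 ratio of -1.19 ± 0.27 (SD, n = 2; limma adjusted p = 0.000274), or 2.28 times as much Cy3 as Cy5 signal. CYCD6;1 (AT4G03270), a D-type cyclin of the formative division that gives cortex and endodermis, had its lowest window at chromosome 4, 1434282 to 1434965 (-0.996 ± 0.66, adjusted p = 0.0041). Its 2 arrays differed, with -0.53 on replicate 1 and -1.46 on replicate 2. MIR165a (AT1G01183), a precursor of the microRNA that limits class III HD-ZIP transcripts, reached -0.72 ± 0.16 (adjusted p = 0.0332) at chromosome 1, 79385 to 80046. JKD (AT5G03150), another IDD zinc-finger gene, reached -0.70 ± 0.08 (adjusted p = 0.0366) at chromosome 5, 742309 to 743002. Over all 11580 gene neighbourhoods with windows, 708, or 6.11%, held such a lower window. That share is no matched comparison, since the 4 genes had 16 to 35 windows each against a median of 9. The median of the lowest windows of the 4 genes, -0.86, lay at percentile 0.1 of 10000 random lists matched on the number of windows, a percentile added after the data were seen. Averaged over whole neighbourhoods none of the 4 passed: MGP had -0.77 (adjusted p = 0.0592), MIR165a -0.27 (0.337), CYCD6;1 -0.21 (0.449) and JKD -0.13 (0.692). The camera test over mean values of whole neighbourhoods also placed this list lower (adjusted p = 0.0368), but not with only probes well above background (adjusted p = 0.0655). With an estimated correlation the list missed as well (camera adjusted p = 0.663). All 12 lists had that same adjusted p, and the correlation was estimated with 1 residual degree of freedom, so that miss decides nothing. SHR itself (AT4G37650) had neither a higher window (0.42 ± 0.16, adjusted p = 0.301) nor a lower window (-0.17 ± 0.10, adjusted p = 0.764) that passed.

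**Figure D1:**
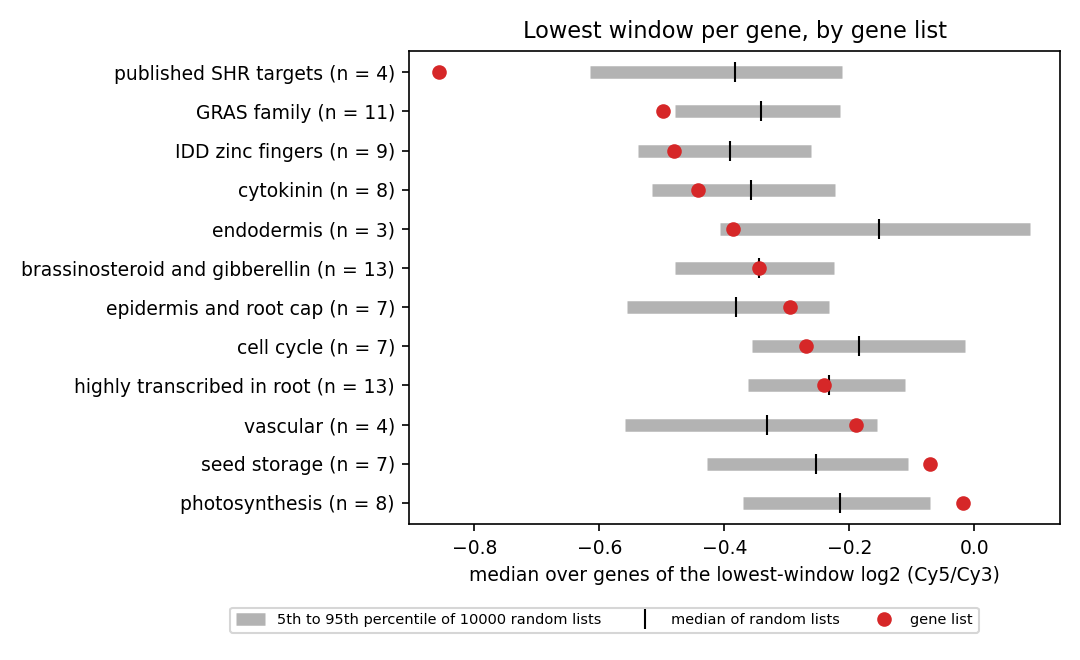
Median over the genes of each list of the lowest-window log2 ratio (Cy5 over Cy3, mean of 2 arrays; points), with the 5th to 95th percentile (grey bars) and the median (ticks) of 10000 random lists matched on the number of windows. The published SHR targets, at -0.86, lie at percentile 0.1 of their random lists.

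Across the whole array, windows that were lower in the DNA labelled ChIP outnumbered those that were higher. A window was the mean over all probes within 400 bp of a probe, with at least 3 probes. Of 203849 windows, 2655 were lower and 374 were higher at a limma adjusted p under 0.05, so 87.7% of the called windows were lower. That share was 73.6% after normexp background correction, where at an unadjusted p under 0.05 limma had 13189 lower and 12939 higher windows. At least 2-fold, 334 windows in 112 regions were lower and 6 windows in 4 regions were higher. The lower regions were also wider: 51 of the 112 held 3 or more windows, with up to 13 windows and 2392 bp, while none of the 4 higher regions held more than 2 windows. At 1.5-fold, 166 of 818 lower regions (20.3%) and 3 of 185 higher regions (1.62%) held 5 or more windows. In the part of the genome with named genes, 27874 of all 98445 windows (28.3%) lay inside annotated genes. Of called windows under 2-fold, 165 of 1362 lower ones (12.1%) and 70 of 133 higher ones (52.6%) did. Of windows at least 2-fold lower, 28 of 177 (15.8%) did. Since windows overlap, a test added after these values were seen took 1 window per region: 11 of 64 (17.2%) lay inside genes, against 27611 of 96772 uncalled windows (28.5%; odds ratio 0.520, 95% interval 0.245 to 1.007; Fisher's exact test, two-sided, p = 0.0516). Taking 1 uncalled window per 2000 bp raised the comparison share to 36.4%. The odds ratio was then 0.362 (95% interval 0.170 to 0.702, Fisher's exact test, two-sided, p = 0.00102). Both odds ratios lay below 1, and only the second interval excluded 1. Over single probes, 1228 of 231022 were lower and 474 higher, but only 17 and 28 with features left out whose 2 channels were both at surrogate values, and 0 and 339 with a trended and robust variance prior. At an unadjusted p under 0.05, lower probes still outnumbered higher ones in these 2 settings (14707 against 11957, and 11892 against 9137). No window kept its call with the deposited value table, which holds the authors' log ratios, or with that prior. With the deposited value table all 334 windows stayed below 0. Replicate 2 alone had 1775 windows at least 2-fold lower and 247 higher, and replicate 1 alone 239 and 56.

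**Figure D2:**
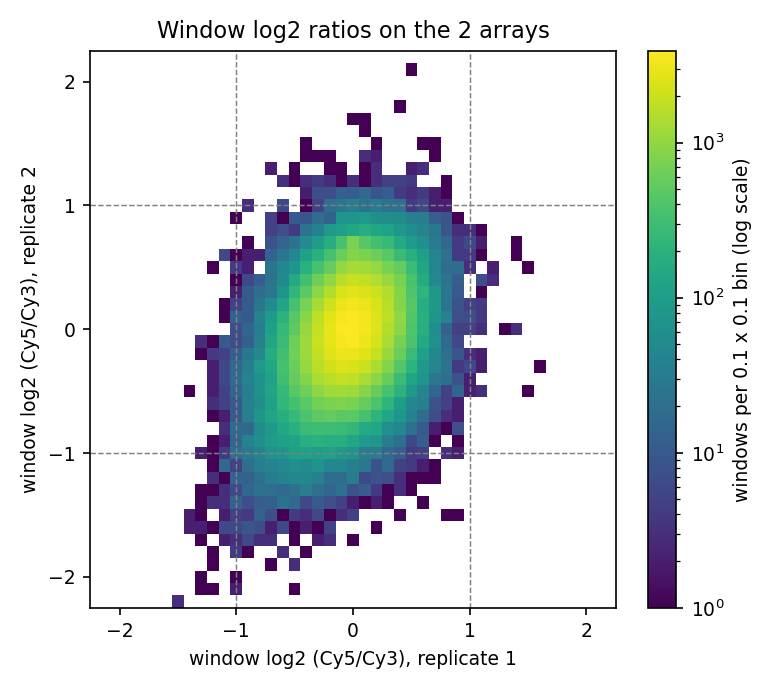
Number of windows by log2 ratio (Cy5 over Cy3) on replicate 1 (x axis) and replicate 2 (y axis), in bins of 0.1 by 0.1, with dashed lines at 2-fold. In the lower left corner 89 windows were at least 2-fold lower on both arrays, and in the upper right corner there were 0.

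The 2 arrays resembled each other weakly over all windows and more closely among the lowest ones. Pearson's r between arrays was 0.288 across windows (Spearman's rho 0.255) and 0.320 across gene neighbourhoods (rho 0.303). Windows and genes are not independent replicates. Among the 2038 lowest windows of each array, 428 were shared, 21.0 times the 20.4 of independent lists. Among the 2038 highest windows, 123 were shared, 6.04 times that number. Among the 500 lowest gene neighbourhoods of each array 120 were shared, and among the 500 highest 80, against 22.2 for independent lists.

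Of the 112 regions at least 2-fold lower, 64 lay where genes could be named. The lowest of all, at chromosome 2, 1137304 to 1137574, between MRH6 and ACR5 (AT2G03730, an ACT-domain protein), had a log2 ratio of -1.83 ± 0.47 (n = 2, adjusted p = 4e-07), or 3.55 times as much Cy3 as Cy5. Among regions where genes could be named, the window between AT1G18290 and NUDT4 (AT1G18300, a Nudix hydrolase), at chromosome 1, 6299288 to 6299622, followed with -1.53 ± 0.16 (adjusted p = 7.56e-06). In AHL19 (AT3G04570, an AT-hook DNA-binding protein) the window at chromosome 3, 1230500 to 1230931, had -1.47 ± 0.73. Further regions whose genes are not named here included chromosome 1, 18683406 to 18684972, with 9 windows and -1.66 ± 0.57 at its lowest, and chromosome 2, 19100447 to 19102053, with 13 windows and -1.44 ± 0.20. Ranked by the weaker of the 2 arrays, a ranking chosen after the values were seen, the lowest neighbourhoods also included windows between these pairs of genes. They were AT4G25550 and LAF1 (AT4G25560, a MYB factor of light signalling, -1.38 ± 0.27), and AT1G14330 and AT1G14340 (-1.41 ± 0.42). Further pairs were AT1G19170 and JAZ1 (AT1G19180, a repressor of jasmonate responses, -1.19 ± 0.06), and TMAC2 and PTF1 (AT3G02150, a TCP factor, -1.14 ± 0.03). The others were AT3G20340 and AT3G20350 (-1.12 ± 0.01), AT3G15530 and AT3G15534 (-1.10 ± 0.06), and AT4G16444 and AT4G16447 (-1.08 ± 0.02). The adjusted p of these windows was at most 0.0007. The windows at ACR5, NUDT4, AHL19, AT1G14330, AT3G20340 and AT4G16444 held 3 probes, the minimum. Those at JAZ1, AT3G15530, LAF1 and PTF1 held 4 to 7.

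Beside MGP, a region of 13 windows, from 970713 to 973104 on chromosome 1, lay between MGP and GRXS13 (AT1G03850, a glutaredoxin). A second region of 6 windows, from 978098 to 979247, lay between GRXS13 and PHB2 (AT1G03860, a mitochondrial prohibitin) and reached -1.29 ± 0.30 (adjusted p = 9.57e-05). Over whole neighbourhoods, GRXS13 (-0.79, adjusted p = 0.0492), PHB2 (-0.88, adjusted p = 0.0492) and LAF1 (-1.06, adjusted p = 0.031) were among the 9 neighbourhoods that were lower, with 1 that was higher, of 11270 tested. These counts depended on the processing: lower and higher neighbourhoods numbered 0 and 0 after centring on the mode, 1 and 0 after normexp, 3 and 0 without saturated features, 88 and 24 after loess, 99 and 27 with the deposited value table, and 392 and 118 with the GC trend removed.

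**Figure D3:**
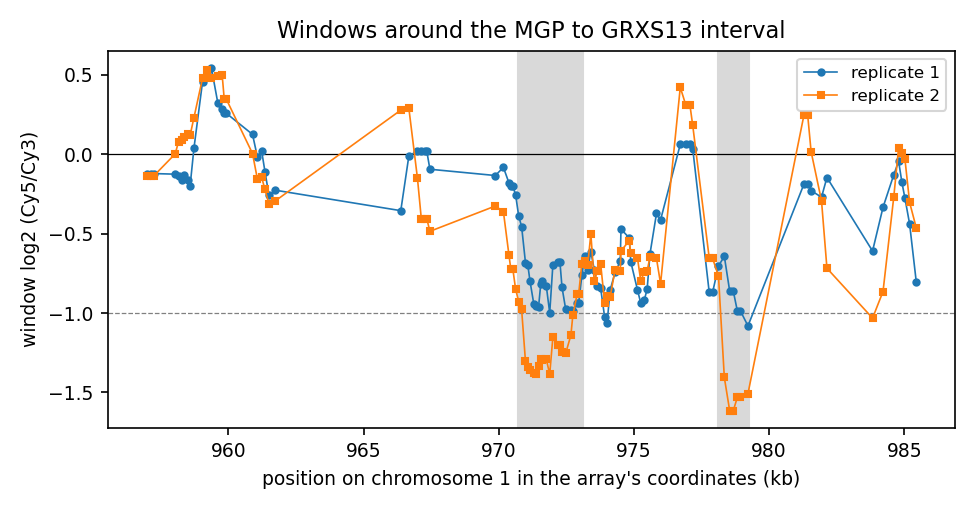
Window log2 ratios (Cy5 over Cy3) of replicate 1 (circles) and replicate 2 (squares) along chromosome 1 in the array's coordinates, with the 2 regions at least 2-fold lower shaded. Both arrays fell to about -1 or below within the regions that start at 970713 and at 978098.

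Windows higher in the DNA labelled ChIP were few and narrow. Of the 4 regions at least 2-fold higher, the one where genes could be named lay at chromosome 1, 8288962 to 8289486, beside AT1G23340 (1.06 ± 0.49, adjusted p = 0.00165). The other 3 lay at chromosome 2, 15582906 to 15583415 (1.29 ± 1.15), at chromosome 3, 11378278 to 11378994 (1.08 ± 0.58), and at chromosome 2, 7213402 to 7214050 (1.07 ± 0.51). The first of these rested on replicate 2, with 2.103 against 0.475 on replicate 1. The regions at least 2-fold lower leaned on replicate 2 as well. At their lowest windows, 104 of the 112 were lower on replicate 2, with medians of -0.90 on replicate 1 and -1.38 on replicate 2. In the window beside AT1G23340, all 3 probes on replicate 2 and 2 of the 3 on replicate 1 were at surrogate values in both channels, which give a fixed ratio. Of the 6 windows at least 2-fold higher, 3 were still called without such features and 0 with only probes well above background. The highest windows of the 4 regions held 3 probes each, the minimum, so a window that lost a probe was no longer tested. How many of the 6 were still tested was not counted, so the lost calls cannot be read as failed tests.

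Among the gene lists fixed before the data were examined, no member of any list had a called higher window. Such windows were rare, in 69 of all 11580 gene neighbourhoods, so their absence from short lists says little. No list other than the published targets passed the camera test. That list passed it with the preset correlation and missed with an estimated one (adjusted p = 0.663) and with only probes well above background (adjusted p = 0.0655). Of 9 measured IDD genes, 3 had a lower window, namely MGP, JKD and IDD5 (AT2G02070, -0.68 ± 0.20, adjusted p = 0.0462), and 4 when adjusted over the list alone. The highest IDD window, at SGR5, was not called (0.61 ± 0.58, adjusted p = 0.11). Of 11 GRAS genes, 3 had a lower window, and 3 when adjusted over the list alone: the DELLA repressors RGA1 (AT2G01570, -0.88 ± 0.29, adjusted p = 0.00731) and GAI (AT1G14920, -0.77 ± 0.42, adjusted p = 0.0252), and HAM3 (AT4G00150, -0.76 ± 0.27, adjusted p = 0.0237). The median lowest window of the GRAS list lay at percentile 3.21 of its random lists and that of the IDD list at percentile 15.9, neither adjusted for the number of lists. For the median highest window, the percentile planned in advance, the endodermis list of 3 genes lay at 0.1 and the published targets at 4.22. The other lists lay between 17.65 and 94.62, and none of these percentiles was adjusted either. The highest GRAS window, also at HAM3, was not called (0.46 ± 0.04). Of 8 cytokinin genes, 2 had a lower window, IPT5 (AT5G19040, a cytokinin-synthesis gene, -0.76 ± 0.43, adjusted p = 0.0257) and the receptor HK3 (AT1G27320, -0.68 ± 0.02, adjusted p = 0.0469), with 4 adjusted over the list alone.

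In the list of brassinosteroid and gibberellin genes, 2 of 13 had a lower window, ROT3 (AT4G36380, a cytochrome P450, -0.72 ± 0.55, adjusted p = 0.0429) and GA2OX6 (AT1G02400, -0.68 ± 0.19, adjusted p = 0.0452), with 0 adjusted over the list alone. The endodermis list had 1 of 3, GSO1 (AT4G20140, a receptor kinase of the Casparian strip, -0.82 ± 0.50, adjusted p = 0.0176). The cell-cycle list had 1 of 7, CYCD6;1, which the list of published targets also holds. The highly transcribed root genes had 1 of 13, ACT7 (AT5G09810, -0.75 ± 0.35, adjusted p = 0.0264), and the seed-storage genes 1 of 7, CRU2 (AT1G03880, -0.82 ± 0.30, adjusted p = 0.0137). In each of these last 4 lists the count adjusted over the list alone was also 1. The vascular (4 genes), epidermis and root-cap (7 genes) and photosynthesis (8 genes) lists had none, over all windows or adjusted over the list alone. Their lowest windows, at NAC007 (-0.33 ± 0.06), RSL4 (-0.38 ± 0.23) and LHCB2.1 (-0.54 ± 0.43), were not called. At the other end, the median lowest windows of the photosynthesis and seed-storage lists lay at percentiles 98.79 and 97.99 of their random lists. The highest windows of the remaining lists, at CKX4, ACL5, GA20OX1, CYCD4;2, CASP4, FEZ, LHCB2.1, SESA3 and TUB6, ran from 0.26 at ACL5 to 0.55 at GA20OX1 and were not called over all windows. Adjusted over the list alone, 2 IDD genes and 1 endodermis gene had a higher window.

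The core of the site bound by IDD proteins, TTTGTC, was counted on either strand in the probes of each window. It occurred in 28 of the 112 regions at least 2-fold lower (25%) and in 214 of 1120 windows matched on GC content and number of probes (19.1%), an odds ratio of 1.41 with a 95% interval of 0.863 to 2.25 (Fisher's exact test, two-sided, p = 0.136). Over all 818 called lower regions it occurred in 189 (23.1%), against 20.4% of matched windows (odds ratio 1.17, Fisher's exact test, two-sided, p = 0.070), and outside genes in 91 of 391 (23.3%), against 21.2% (odds ratio 1.13, p = 0.365). Over all 185 called higher regions it occurred in 23, against 311 of 1827 matched windows (odds ratio 0.692, Fisher's exact test, two-sided, p = 0.12). None of these differences passed the test at 0.05.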

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

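Of the alternatives, the omission of features with surrogates in both channels was chosen after the data were seen. No called value of a named gene turned its sign. All 334 windows at least 2-fold lower that an alternative still tested stayed below 0 in each of them, which is fixed where an alternative leaves the window means as they are (the trended and robust prior, for example) or moves them all down (centring on the mode). Lower windows outnumbered higher ones wherever windows were called, which the shift also fixes for the mode. Called probes went the other way in 3 settings, given below, although at an unadjusted p under 0.05 lower probes outnumbered higher ones in each of them. The number of calls varied widely. The cause was not tested unless stated. With only probes well above background, 346 windows were at least 2-fold lower, and 234 of the 334 were among them (271 were still tested). The ratio pairs the 2 kinds of DNA within each array, and with 1 group no further pairing was possible.

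No window passed with the deposited value table (0 higher and 0 lower at any size or at 2-fold, 0 regions and 0 neighbourhoods with such windows in either direction), and no probe passed (0 and 0). At an unadjusted p under 0.05 limma still had 7738 higher and 17453 lower windows there. Neighbourhood means gave 27 higher and 99 lower, and r between arrays was 0.304 over windows. With a trended and robust prior, 0 windows were higher and 0 lower, at any size or at 2-fold, with 0 regions of either kind, 0 and 0 neighbourhoods holding one, 0 lower and 339 higher probes, and 0 higher and 0 lower neighbourhood means. Unadjusted, 6648 windows were higher and 13188 lower.

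Centring on the mode moved the median of all windows to -0.38, because the mode of replicate 2 (0.70) lay at its surrogate values (0.71). Under it 0 windows were higher and 24 lower, all 24 at 2-fold (0 higher), in 11 lower and 0 higher regions and 6 neighbourhoods (0 with a higher window). Probes gave 0 and 0, neighbourhood means 0 and 0, and 222 windows were 2-fold lower on both arrays. Unadjusted, 15127 windows were lower and 1 higher.

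After normexp, 894 windows were lower (unadjusted, 13189 lower and 12939 higher windows, and 685 lower and 764 higher neighbourhoods), 81 at 2-fold lower and 1 higher, in 28 lower and 1 higher regions, with 20 neighbourhoods holding a lower window and 0 a higher one. Neighbourhood means gave 1 lower and 0 higher, probes 0 and 0 (10687 lower and 14034 higher unadjusted), 12 windows were 2-fold lower on both arrays, and r was 0.277 over windows and 0.286 over neighbourhoods. Of its 81 windows, 80 were among the 334.

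After loess, 1123 windows were lower and 97 higher, 212 and 3 at 2-fold (205 of them among the 334), in 64 lower regions, with 52 neighbourhoods holding a lower window and 0 a higher one. Neighbourhood means gave 88 lower and 24 higher, probes 0 and 0 (14176 lower and 9800 higher unadjusted), and 56 windows were 2-fold lower on both arrays. There r was 0.214 over windows and 0.233 over neighbourhoods, and 76 of the highest windows were shared. With the GC trend removed, 571 windows were higher, neighbourhood means gave 392 lower and 118 higher, probes 2341 lower and 889 higher, and r was 0.278 and 0.3004.

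With only probes well above background, probes gave 28 lower and 32 higher, 2 regions were higher, 0 neighbourhood means were higher (588 unadjusted), 3 windows were 2-fold higher on both arrays, and r over windows was 0.305. The camera test of the published targets then missed the threshold (adjusted p = 0.0655), as it did with an estimated correlation (0.663); its adjusted p was between 0.0101 and 0.0459 under the other settings. Without features at surrogates in both channels, probes gave 17 lower and 28 higher, neighbourhood means 109 lower and 32 higher, 2 windows were 2-fold higher on both arrays, and r over windows was 0.306. Without saturated features, neighbourhood means gave 3 lower and 0 higher (522 higher unadjusted).

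Half-widths of 250 bp gave 244 higher windows, 194 lower regions, 173 neighbourhoods with a lower window and 2 windows 2-fold higher on both arrays. Half-widths of 600 bp gave 63 lower regions, 52 neighbourhoods with a lower window and 56 windows 2-fold lower on both arrays. Window medians gave 142 higher windows, 147 neighbourhoods with a lower and 2 with a higher window, and 152 windows 2-fold lower on both arrays. An adjusted p of 0.01 gave 844 lower and 43 higher windows, 240 lower and 104 higher probes, and 0 lower and 0 higher neighbourhood means. A 1.5-fold minimum gave 2655 lower and 374 higher windows, 818 lower and 185 higher regions, and 708 and 69 neighbourhoods. At least 5 probes per neighbourhood gave 148 lower and 28 higher means. Top lists of 5% of windows shared 2455 lowest and 1164 highest windows, and lists of 1000 neighbourhoods shared 295 and 208. Without one replicate, windows at 2-fold on the other array ranged from 239 to 1775 lower and from 56 to 247 higher.

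Of the values for single named genes, 615 kept their side of the threshold, 119 fell short of it, 58 of these in the deposited value table or with the trended and robust prior, and 1 passed it, the highest window of SGR5 (AT2G01940) with a half-width of 250 bp. MGP (AT1G03840) missed the threshold with centring on the mode, the deposited value table and the trended and robust prior, and its lowest window ranged from -0.99 to -1.56. CYCD6;1 (AT4G03270) also missed it after normexp. MIR165a (AT1G01183) and JKD (AT5G03150) missed it in these, after loess, with window medians, at an adjusted p of 0.01 and without surrogates, and MIR165a also with a half-width of 600 bp.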

Other observations

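The percentile of the published targets' lowest windows, the tests of the GC and intensity trends, of surrogate values, of neighbouring probes and of region positions inside genes, the count of other motifs and the symbol families were chosen after the results they bear on were seen. Other genes whose neighbourhoods held a window at least 2-fold lower in the DNA labelled ChIP, picked after their values were seen, include DOF2 (AT3G21270, -1.15 ± 0.50, SD, n = 2), WRKY47 (AT4G01720, -1.11 ± 0.30), MYB108 (AT3G06490, -1.07 ± 0.26), the abscisic acid receptor PYL5 (AT5G05440, -1.14 ± 0.27), the ethylene-synthesis gene ACS7 (AT4G26200, -1.19 ± 0.55), the sugar transporter STP1 (AT1G11260, -1.30 ± 0.83) and the glutaredoxin GRX480 (AT1G28480, -1.11 ± 0.34). In limma's test each passed at an adjusted p of 0.001 or less. Except at MYB108, whose window was centred inside the gene, these windows lay in gaps shared with another gene, and the values do not tell the neighbours apart. The other genes were GLTP3 beside DOF2, CRK beside WRKY47, AT5G05430 beside PYL5, AT4G26210 beside ACS7, SYP125 beside STP1 and SYP61 beside GRX480. Of 48 gene-symbol families with at least 10 measured members, none held lower windows more often than the 6.11% of all neighbourhoods after adjustment (Fisher's exact test, not matched on windows per gene); the lowest adjusted p was 0.155, for 4 of 11 NUDT genes, and WRKY genes had 5 of 29 (adjusted p = 0.471).

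The first pattern is that regions lower in Cy5 were more numerous and wider than regions higher in Cy5, although the labels put the precipitated DNA in Cy5. A trend of the ratio with GC content or intensity is argued against as the whole cause: 298 of the 334 windows at least 2-fold lower were still called with the GC trend removed and 205 after loess. Surrogate values near background are argued against as the whole cause too, since 277 of the 334 were still called without features at surrogates in both channels. Background handling more widely stays open. After normexp background correction 80 of the 334 were still called at 2-fold, though all 334 stayed below 0. At an unadjusted p under 0.05 limma then had 13189 lower and 12939 higher windows, 10687 and 14034 probes, and 685 and 764 neighbourhoods. Over-representation of open or highly transcribed chromatin in the Cy3 DNA stays open. The lowest windows of the 13 highly transcribed root genes lay at percentile 45.84 of random lists, past the bound set in advance against high transcription. That list holds no measure of open chromatin, so the bound could not decide that part. The photosynthesis and seed-storage lists lay at percentiles 98.79 and 97.99, with lowest windows less low than in most random lists. Expression was not measured here, so whether transcription is behind that difference was not tested. The share of lower regions inside genes does not decide about open chromatin either, because that share is no direct measure of it. Both odds ratios lay below 1. The odds ratio was 0.520 against all uncalled windows, with an interval that reached above 1. Against 1 uncalled window per 2000 bp the odds ratio was 0.362, with an interval of 0.170 to 0.702, which lies below 1. Another candidate explanation that stays open is that the precipitated DNA was in the Cy3 channel, opposite to the labels. The test written for it in advance, of the IDD core TTTGTC in the lower regions, gave an odds ratio of 1.41 with an interval that reached below 1, and probes cover only part of each region. The published targets lay at percentile 0.1, but low ratios at these loci prompted the idea and only 4 genes carry that test, so it is no separate support. Without a dye swap or a line lacking GFP a dye or input effect at these loci is not excluded, and with 1 group the design gives no biological contrast for this pattern.

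The second pattern is the correlation of window log2 ratios between arrays, 0.288, which effects of single probe sequences could give. With the GC trend removed, r across arrays was 0.243 for the same probe and still 0.102 between neighbouring probes, at a median distance of 154 bp, and 0.0484 between probes 8 apart, at 1368 bp. Sequence effects of single probes therefore do not give the whole correlation, while the drop from 0.243 to 0.102 leaves room for a part.

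The third pattern is a motif. Of 5 short sequences counted in the probes of 3 classes of region, the G-box core CACGTG had the lowest adjusted p: it occurred in 37 of 818 called lower regions (4.52%) and in 1.59% of matched windows (odds ratio 2.93, adjusted p = 4.95e-06 over 15 Fisher tests), and in 1 of 185 called higher regions. Among the 112 regions at least 2-fold lower it occurred in 5, which did not pass (adjusted p = 0.0696). Lying outside rather than inside genes does not account for it, since among windows outside genes the odds ratio was 3.20 (95% interval 1.76 to 5.58, 18 of 391 regions against 1.48%). Distances from transcription start sites were not analysed, so position within the gaps between genes was not tested. GAGAGA was less frequent in called lower regions (9.90% against 13.3%, adjusted p = 0.041). AAACCCTA passed in no class. GGGCCC was in 2 of 112 regions at least 2-fold lower against 0 of 1120 matched windows (adjusted p = 0.041), too few to weigh, and over all 818 lower regions it did not pass (6 against 25 of 8180 matched windows, adjusted p = 0.143). Whether bound factors or base composition beyond GC content gives the G-box excess may be asked of a genome sequence, which was not used here.

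That IDD genes themselves lie near lower windows more often than chance was left open, with the list's median lowest window at percentile 15.9 of its random lists.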
